A study of Zea mays with 4 samples.

How the data were processed

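Small RNAs were sequenced from maize (Zea mays, inbred line B73) seedlings in 4 libraries, with 1 library for each of control, drought, cold and salt. Per the labels' protocols, total RNA was size-fractionated on a denaturing gel between 18 and 30 nt, ligated to 3' and 5' adaptors, reverse transcribed and amplified. No adaptor trimmer, aligner, genome build or quality filter is given in the sources used here. The deposited files hold, for each library, every distinct sequence (called a tag below) with its raw read count, as judged from the values: no header, unique sequences of 17 to 31 nt, and whole numbers from 1 upward. These counts carry no molecular identifiers, so PCR copies of one molecule are counted as separate reads. Intervals cover counting error only, except the ranges printed with medians over families or tags, which reflect the spread between members.

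The 4 tables were joined on the exact sequence. Reads of 18 to 30 nt made up the library total, and values are given as RPM, the read count scaled to a library total of 1000000 such reads. A fixed list of 29 entries (28 conserved miRNA families and the TAS3-derived tasiR-ARF) was written, with mature sequences from general knowledge, before the data were examined. Reads of 19 to 24 nt that contain positions 3 to 18 of a listed mature sequence were counted for that family. The ratio of 2 libraries has an exact conditional binomial (Clopper-Pearson) interval at 95%, and shares have Clopper-Pearson intervals. A family was called higher or lower when its ratio was at least 2 or at most 0.5, the interval excluded 1 and the 2 libraries held at least 100 of its reads together. With 1 library per condition there is no replicate check. No p-value is given, and a call compares 2 libraries, not the conditions.

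Families were grouped before the data were examined into lists for development and hormone signalling, copper, nutrients, small RNA machinery, tasiRNA and other. A list's median log2 ratio, taken over the most abundant tag of each family with 0.5 read added, was ranked among 10000 random lists of tags of 20 to 22 nt outside the families, each drawn from the 200 tags nearest in mean RPM. The pool held 76988 tags with at least 20 reads over all libraries. The percentile describes these libraries only. The random tags were not matched on length, and ratios to control differed by length. Among well-read tags outside the families, the drought median was 1.03 at 21 nt and 1.67 at 22 nt, and the cold median 4.01 at 20 nt and 1.53 at 21 nt. A low percentile can therefore partly reflect length or a gap between families and other tags. The named items are, per comparison, the families called higher or lower, the 10 families with most reads, and the 3 highest and 3 lowest other tags of 20 to 24 nt among those with at least 1000 reads in the 2 libraries. Ranked tags at least 50-fold above every other library are given without sequence, because their organism could not be checked; this threshold was lowered from 100-fold after the data were seen, so that it covered the 3 highest cold tags. The miR396-type tag, the miR156 star strand, the miR167 forms, 4 tRNA-like fragments and the nested tags were added after their values were seen. The 5.8S rRNA search sequence was extended at its 5' end after its first form was found to miss leading tags. The first form is given beside it for the cold library and, by length, for drought. miRNA, tRNA and rRNA names rest on sequences known from general knowledge, not on a match to an annotation.

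No genome sequence was used, so tags were not placed on chromosomes and the genomic origin of reads was not analysed here. The RefSeq gene table of assembly Zm-B73-REFERENCE-NAM-5.0 lists 164 miRNA genes and served only to count annotated genes per family; 27 of the 29 entries had at least 1. No tag was assigned to a single gene, since family members share mature sequences.

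The ratio and interval code was tested on counts simulated for 2283 real tags of 20 to 22 nt from their means and the library sizes. For cold against control, 98% of the tags set to a ratio of 0.3333 and 100% of those set to 3, 4 or 0.25 were recovered, and 95.4% of intervals covered the true ratio. Alternatives covered scaling (reads of 20 to 24 nt, reads of 21 nt, reads outside the families, the median family ratio, edgeR's TMM factors over 14652 tags), the family definition, the read minimum and the fold size. Scalings of the ratios between stresses were added after the data were seen. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.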

Results

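Small RNAs were profiled in 14-day-old maize seedlings that were left untreated or exposed to 1 of 3 abiotic stresses. Water was withheld for about 10 days (drought), plants were kept at 4 °C for 24 hours (cold), or they received 300 mM NaCl for 24 hours (salt). The control library held 12906232 reads in 6495919 distinct tags, drought 11167272 reads in 5306853 tags, cold 12071862 reads in 5183333 tags and salt 11395028 reads in 5082266 tags. Between 82.2% (control) and 83.1% (cold) of the distinct tags were read a single time. With 3 reads taken as the limit, a tag with 0 reads could have been present at up to 0.233 RPM in control and 0.270 RPM in drought, the highest limit of the 4. The upper end of the Clopper-Pearson interval at 0 reads is higher, at 0.286 RPM in control and 0.332 in drought.

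The first comparison concerns the size classes. The 24-nt class, which in plants holds mainly heterochromatic siRNAs, was the most abundant in each library and made up 53.5% of control reads, 47.5% of drought, 43.2% of salt and 41.5% of cold reads. The 22-nt class stood at 16.7% in control and 22.2% in drought. The 21-nt class, where most canonical miRNAs fall, stood at 10.9% in control, 11.3% in drought, 9.88% in cold and 21.1% in salt. Cold had more short reads: 9.37% of its reads were 19 nt and 6.33% were 20 nt, against 1.96% and 2.21% in control. Counting intervals on these shares are narrow, as for the control 24-nt share of 53.5% on 12885901 reads, but 1 library per condition gives no measure of the spread between seedlings. There were 4.91 reads of 24 nt for each 21-nt read in control, 4.19 in drought, 4.20 in cold and 2.05 in salt. In salt 2 tags made up 53.6% of the 21-nt reads, and by distinct tags cold, not salt, had the lowest ratio.

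**Figure D1:**
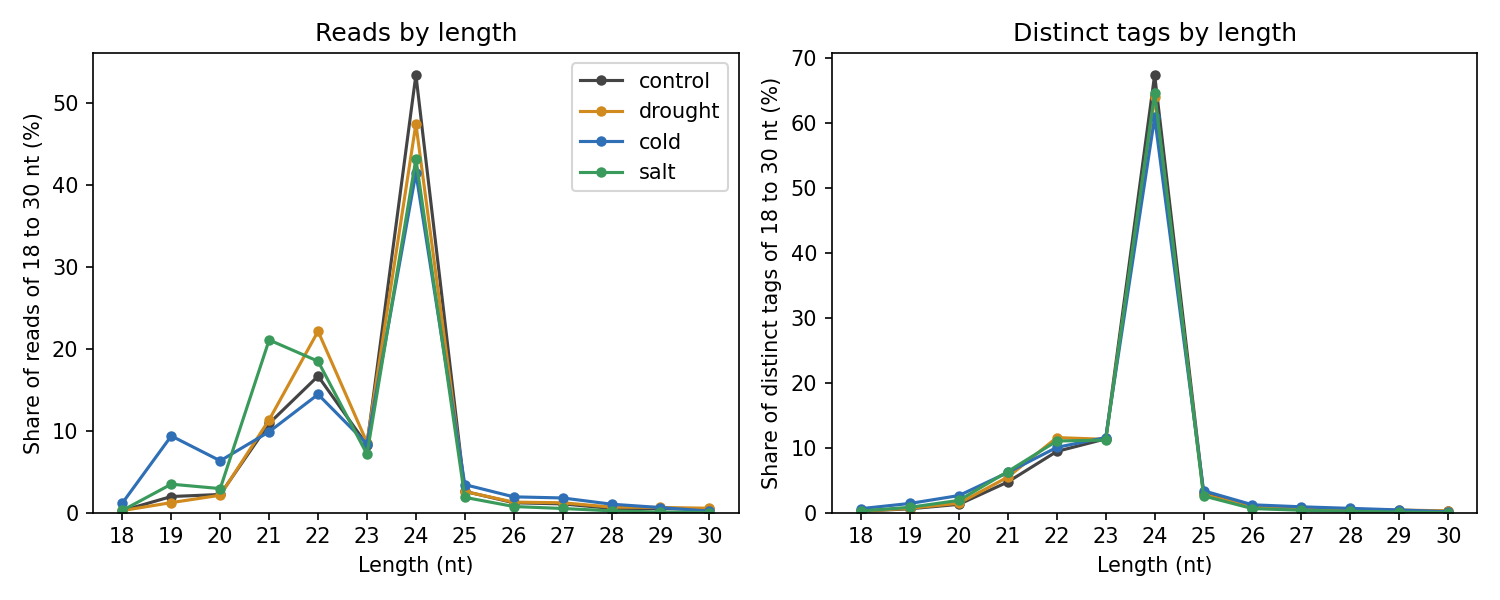
Share (%) of reads (left) and of distinct tags (right) at each length from 18 to 30 nt (x axis), 1 line per library. The 24-nt peak is highest in control at 53.5% of reads, salt has the highest 21-nt share at 21.1%, and cold has the highest 19-nt share at 9.37%.

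Adenine was the first base of 54.5% of 24-nt reads in control and 55.0% to 55.6% in the stress libraries. Among 21-nt reads, uridine led in 64.7% in control, 59.9% in drought, 43.2% in cold and 78.1% in salt. Without the fixed families these shares were 54.9%, 43.9%, 31.3% and 65.9%. A single tag outside the fixed list, TCCACAGGCTTTCTTGAACTG, carried much of the difference: without it and its end variants the shares were 35.0%, 31.97%, 27.1% and 37.2%.

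The fixed miRNA families together took 3.12% of reads in control, 4.33% in drought, 2.31% in cold and 8.62% in salt. Of the 29 entries, 28 had at least 1 read, and 25 had the 100 reads required in each comparison with control. miR159, which targets GAMYB transcription factors, had the most reads, followed by miR167, miR168, miR166, miR396, miR164, miR156, miR169, miR390 and miR171. miR397, miR529 and miR2118 had 6, 72 and 41 reads over all 4 libraries, and no miR2275 read was found.

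In drought, 4 families were at least 2-fold lower than in control and 0 were at least 2-fold higher. miR169, which targets NF-YA transcription factors and has 18 genes in the annotation, stood at 165 RPM against 471 RPM, a ratio of 0.350 (95% interval 0.332 to 0.369). miR528, a monocot miRNA with copper oxidase targets, stood at 21.6 against 62.01 RPM (ratio 0.348, interval 0.300 to 0.403). miR398, which targets copper/zinc superoxide dismutase, had 31 reads against 100 (ratio 0.359, interval 0.232 to 0.542), and miR1432 had a ratio of 0.419 (interval 0.343 to 0.508). The drought ratio was 1.84 for miR168, which targets AGO1, 1.67 for miR167, which targets auxin response factors, 1.54 for miR156, a regulator of SPL genes, 1.39 for miR159 and 1.32 for miR164, none of which reached 2-fold. It was 1.04 for miR166, 0.969 for miR171, 0.668 for miR390 and 0.574 for miR396.

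By list, 2 of the 3 copper families with enough reads (miR398 and miR528) were lower in drought and 0 were higher. The third, miR408, had a ratio of 0.684. The median log2 ratio of the copper list was -1.48 over families. Over top tags it was -1.37, at percentile 0.09 of matched random lists, whose own median was 0.42. In the nutrient list (miR395, miR399 and miR827) 0 of 3 reached 2-fold, with a median log2 ratio of -0.70 over top tags at percentile 1.32 (random lists 0.52). Of the 15 development and hormone families 1 was lower, 0 were higher and 14 were neither, with a median log2 ratio of -0.02 over top tags at percentile 16.2 (random lists 0.24). Both machinery families, miR162 (ratio 1.33) and miR168, stayed under 2-fold (percentile 78.6). tasiR-ARF, a TAS3 product that targets auxin response factors, had a ratio of 0.528 (interval 0.434 to 0.641; percentile 3.45). miR1432, the single member of the list of others with enough reads, lay at percentile 0. These counts depend on the scaling: with TMM factors all 3 copper families, 2 nutrient families (miR395 and miR827), 5 development and hormone families (miR169, miR319, miR390, miR394 and miR396) and tasiR-ARF were lower. Relative to the median family miR167 and miR444 of the development and hormone list and miR168 of the machinery list were higher, and miR1432 was no longer called lower.

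Outside the fixed families, 269 tags of 20 to 24 nt were deep enough to rank in drought, of which 29 were at least 2-fold higher and 21 at least 2-fold lower. The 22-nt tags held 19 of the higher ones, with 3 lower among 78 and a median ratio of 1.67. All 3 of the highest were 22 nt: AGAAGTGTGCTTTAGAAAAACT at 105 against 7.06 RPM (ratio 14.9, interval 12.1 to 18.7), AAAGCCTGTAGATCTTGATGTT with a ratio of 5.51 and AGAAAAATTTTTGGATAGTGGC with a ratio of 5.37. The 3 lowest were TAATTCATGATCTGGCATGTACA (ratio 0.164), TAATTCATGATCTGGCATGTACAG (ratio 0.177) and TAATTCATGATCTGGCATGT (ratio 0.191), which share their 5' end. Fragments of 5.8S rRNA were 1.54-fold and 5' fragments of tRNA-Gly(GCC) 1.99-fold as abundant as in control. Both ratios differed by length: 1.17 and 1.28 at 18 to 20 nt, but 1.73 and 2.56 at 28 to 30 nt. With the first 5.8S search sequence the ratios at these lengths were 1.27 and 1.07. With edgeR's TMM factors in place of total reads every drought log2 ratio moved by -0.49 and 12 families were lower (the 11 named by list above and miR1432) and 0 higher. Relative to the median family, which lay at a log2 ratio of -0.32, miR167, miR168 and miR444 made 3 higher against 3 lower, a share of 50% higher against 0% per total reads, and miR1432 no longer passed. The listed 21-nt forms of miR1432 had 0 reads in the 4 libraries, exactly or with up to 2 substitutions, so its call rests on tags with other ends.

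In cold, 3 families were at least 2-fold higher than in control and 7 at least 2-fold lower. miR528 stood at 202 against 62.01 RPM (ratio 3.25, interval 3.003 to 3.530) and miR408, which targets plantacyanin-type copper proteins, at 132 against 49.8 RPM (ratio 2.64, interval 2.41 to 2.90). miR394, which targets an F-box gene, had a ratio of 2.07 (interval 1.83 to 2.35). The lower families were miR171 (GRAS targets, ratio 0.359, interval 0.331 to 0.389), miR164 (NAC targets, ratio 0.377, interval 0.363 to 0.392), miR396 (growth-regulating factors, ratio 0.391, or 0.205 with the miR396-type tag described for salt counted in), miR166 (class III HD-ZIP genes, ratio 0.394), miR169 (ratio 0.456), miR827 (ratio 0.485) and miR399, a phosphate-starvation miRNA, with 52 against 114 reads (ratio 0.490, interval 0.346 to 0.686). The cold ratio was 1.92 for miR156, 0.989 for miR159, 0.701 for miR390, 0.675 for miR167 and 0.523 for miR168.

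Of the 15 development and hormone families, 5 were lower and 1 was higher in cold, with a median log2 ratio of -0.51 over families and of -0.76 over top tags, at percentile 0.62 of matched random lists. Those lists had a median of 0.61, and relative to the median family the list lay at -0.033, with 3 higher (miR156, miR393 and miR394) and 0 lower. Because 15 of the 25 families that set the median family belong to the list, a value near 0 there is partly built in. The list had 2 higher and 4 lower on reads of 20 to 24 nt or of 21 nt, and 2 and 3 with TMM factors. In the copper list 2 of 3 were higher and 0 lower. miR398 had a ratio of 0.913, and the list had a median log2 ratio of 1.40 over families and 1.71 over top tags, at percentile 84.5 (random lists 0.19). The nutrient list had 2 of 3 lower (percentile 11.7), miR399 and miR827, but 0 of 3 on reads of 20 to 24 nt, on 21-nt reads, with TMM factors or relative to the median family. By the same count per total reads, the machinery list had 0 of 2 on either side (percentile 12.6). tasiR-ARF had a ratio of 1.23 (percentile 71.2) and miR1432 a ratio of 1.09 (percentile 57.0).

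Outside the families, 200 of 384 ranked tags were at least 2-fold higher in cold and 31 at least 2-fold lower, with a median ratio of 2.20. Among 90 tags of 20 nt, 68 were higher and 1 was lower. The 3 lowest tags were TGCTCACTTCTCTTTCTGTCAGC (ratio 0.110), GCTCACTTCTCTTTCTGTCAGC (560 against 4810 RPM, ratio 0.116, interval 0.113 to 0.119) and TGCTCGCTTCTCTTTCTGTCAGC (ratio 0.135). The second has the sequence known for the miR156 star strand, the strand opposite mature miR156 in the precursor. The 3 highest tags, of 24, 20 and 21 nt and shown without sequence, had 1761, 12113 and 1611 reads in cold against 3, 26 and 4 in control (the first ratio is 630 with an interval of 215 to 3059).

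The fixed 5' tRNA fragments differed from control in cold by tRNA and by length. Fragments of tRNA-Ala stood at 5614 against 1948 RPM (ratio 2.88), with a ratio of 4.49 at 18 to 20 nt, 1.63 at 24 to 27 nt and 1.02 at 28 to 30 nt. Fragments of tRNA-Gly(GCC) stood at 349 against 799 RPM (ratio 0.437), with a ratio of 0.807 at 18 to 20 nt, 0.467 at 24 to 27 nt and 0.277 at 28 to 30 nt. The fixed chloroplast tRNA-His sequence stayed between 2.72 and 4.50 RPM in the 4 libraries. That search sequence is longer than 20 nt, so it could not count reads of 18 to 20 nt. A group of 57 tags with at least 100 cold reads lay at least 50-fold above every other library. Of these, 1 was a 5' fragment of chloroplast tRNA-Arg(UCU) with 0.502% of cold reads, and the other 56, with 0.714%, matched no named sequence and were not assigned to an organism. Fragments of 5.8S rRNA stood at 5638 RPM in cold and 6327 RPM in control (391 and 308 RPM with the first search sequence). Their ratio was 1.86 at 18 to 20 nt and 0.643 at 28 to 30 nt, but 2.06 and 1.49 with the first search sequence, so the direction for long fragments and for the total depended on the search. On reads of 20 to 24 nt every cold log2 ratio moved by 0.18, and with TMM factors by 0.35, giving 4 higher and 4 lower, or 4 higher and 3 lower (50% and 57.1% higher, against 30% per total reads). Relative to the median family, at a log2 ratio of -0.48, 5 families were higher and 0 lower. Under each of these 3 scalings miR156, miR394, miR408 and miR528 were among the higher families. miR164, miR171 and miR396 were lower on reads of 20 to 24 nt and with TMM factors, but not relative to the median family.

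**Figure D2:**
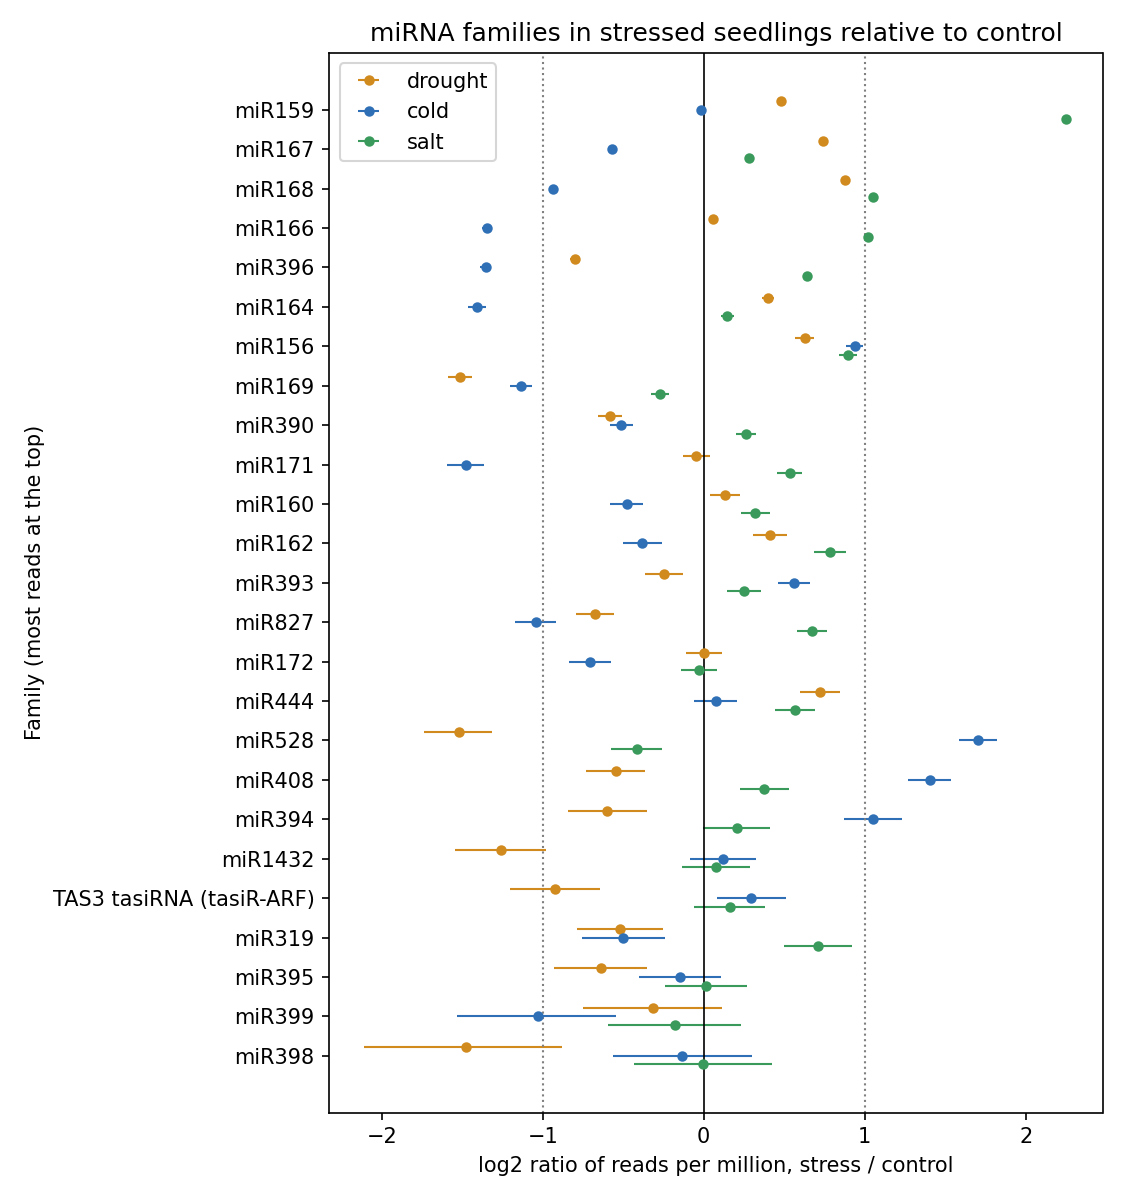
The log2 ratio of RPM, stress over control (x axis), for the 25 families (y axis, most reads at the top) with at least 100 reads in each comparison; bars are 95% counting intervals and dotted lines mark 2-fold. miR528 lies at -1.52 in drought and 1.70 in cold, and miR159 at 2.25 in salt.

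In salt, 3 families were at least 2-fold higher than in control and 0 were at least 2-fold lower. miR159 stood at 55776 against 11724 RPM, a ratio of 4.76 (interval 4.73 to 4.78). miR168 had a ratio of 2.07 (interval 2.05 to 2.10) and miR166 of 2.02 (interval 1.996 to 2.052). The salt ratio was 1.86 for miR156, 1.56 for miR396 (2.30 with the miR396-type tag counted in), 1.45 for miR171, 1.21 for miR167, 1.20 for miR390, 1.11 for miR164 and 0.828 for miR169. The tag with most reads in the 4 libraries together, TCCACAGGCTTTCTTGAACTG, lay outside the fixed list and was singled out after its values were seen. It has the sequence known for the grass-specific form of miR396, and with its end variants stood at 61790 RPM in salt, 26098 in control, 14349 in drought and 4932 in cold. This tag and the main miR159 tag together made up 53.6% of the 21-nt reads in salt, against 33.2% in control, 25.8% in drought and 14.9% in cold.

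By list in salt, 2 of 15 development and hormone families were higher and 0 lower (median log2 ratio 0.34 over top tags against 0.28 for random lists, percentile 68.2). Of the 2 machinery families 1 was higher (percentile 84.8), with miR162 at a ratio of 1.72. The copper and nutrient lists had 0 of 3 members on either side, with median log2 ratios of -0.05 and 0.02 over top tags at percentiles 23.1 and 29.2. tasiR-ARF had a ratio of 1.12 (percentile 44.0) and miR1432 of 1.05 (percentile 26.2). Per 21-nt read miR528 of the copper list, miR399 of the nutrient list and miR169 of the development and hormone list were lower, and the machinery list then had 0 higher, as with TMM factors or relative to the median family.

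Among 235 other ranked tags in salt, 28 were higher and 16 lower. The 3 highest were single-base variants of more abundant tags: TTTGGATTGACGGGAGCTCTG (ratio 9.13), which differs from the main miR159 tag by A11C, TCGCTTGGTGCCGATCGGGAC (ratio 8.02), which differs from the main miR168 tag by A12C, and TCCACAGGCTTTCTTGAAATG (ratio 3.97), which differs from the miR396-type tag by C19A. Positions are counted from 1 at the 5' end, and the base of the more abundant tag comes first. The 3 lowest were TAATTCATGATCTGGCATGTACAG (ratio 0.0929), TAATTCATGATCTGGCATGTACA (ratio 0.0992) and TAATTCATGATCTGGCATGTA (ratio 0.146). Fragments of tRNA-Gly(GCC) had a ratio of 0.326 and those of tRNA-Ala of 0.857. The salt library held few long reads: reads of 28 to 30 nt outside the families and the fixed tRNA fragments had a ratio of 0.205, and tRNA-Gly(GCC) fragments of that length had a ratio of 0.051, against 0.657 at 18 to 20 nt. miR159 was at least 2-fold higher in salt under every scaling tried, whereas miR166 and miR168 were not with TMM factors or relative to the median family (1 higher, 0 lower), nor miR166 on reads of 20 to 24 nt. Per 21-nt read, a total that the miR159 and miR396-type tags dominate, 1 family was higher and 3 lower (25% higher, against 100% per total reads).

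**Figure D3:**
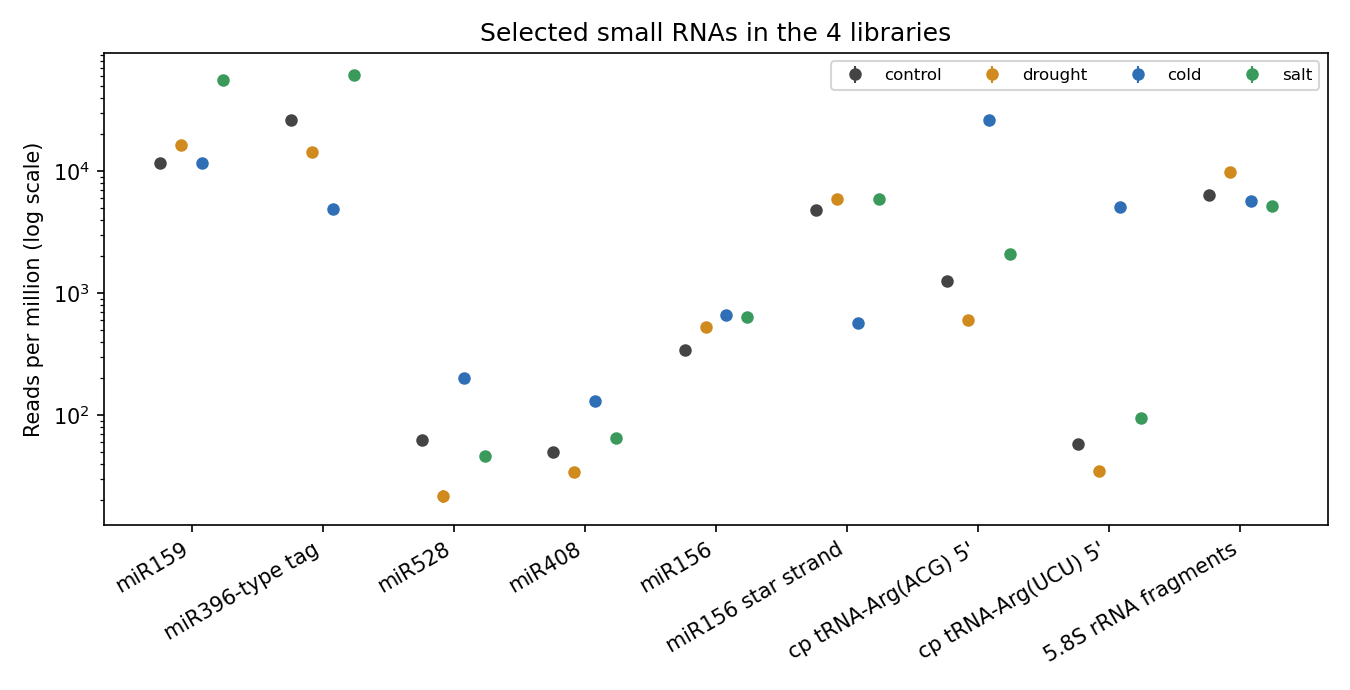
RPM (y axis, log scale) of 9 small RNAs or groups of fragments in the 4 libraries, with 95% counting intervals that are mostly smaller than the points; cp stands for chloroplast. miR159 is at 55776 RPM in salt, and the chloroplast tRNA-Arg(UCU) 5' fragments are at 5034 RPM in cold against 58.4 in control.

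Direct ratios between stress libraries do not share the control. Drought lasted about 10 days but cold and salt 24 hours, so ratios with drought also compare exposures of unlike length. Drought against cold gave 5 higher and 6 lower families: miR528 was 21.6 against 202 RPM (ratio 0.107, interval 0.0933 to 0.122) and miR408 34.1 against 132 RPM (ratio 0.259), while miR168 (ratio 3.51) and miR164 (ratio 3.50) were higher in drought. Drought against salt gave 0 higher and 9 lower, among them miR159 (ratio 0.293), miR398 (ratio 0.361), miR396 (ratio 0.369) and miR169 (ratio 0.422). Cold against salt gave 2 higher (miR528 with a ratio of 4.34 and miR408 with 2.04) and 9 lower, among them miR166 (ratio 0.195) and miR159 (ratio 0.208). These counts depend on the scaling. With TMM factors drought against cold had 0 higher and 10 lower (0% higher, against 45.5% per total reads), and all 9 lower calls of drought against salt ended per 21-nt read (3 higher) and relative to the median family (2 higher), 100% higher in each case against 0%. Cold against salt had 7 higher and 2 lower per 21-nt read (77.8% higher, against 18.2% per total reads), 3 and 6 with TMM factors (33.3%) and 4 and 5 relative to the median family (44.4%). miR528 was higher in cold than in drought and in salt under each of the 5 scalings tried. Against the shared control, miR169 was the single family called lower in both drought and cold per total reads. Its cold call ended on reads of 20 to 24 nt (ratio 0.518), of 21 nt (0.503), with TMM factors (0.580) and relative to the median family (0.635). With TMM factors miR396 was the family lower in both instead (ratio 0.408 in drought and 0.498 in cold). Independent lists of 4 and 7 among 25 families would share 1.12. Simulated unchanged libraries shared 0, but they held counting error only, which hardly reaches 2-fold at 100 reads or more. That 0 therefore says nothing about variation between libraries. With 1 control library the control could not be split, so part of any overlap may come from it.

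Tag sharing was compared after each library was thinned to 11115952 reads. Control then held 5743479 distinct tags, drought 5296351, salt 4977095 and cold 4848466. Of these, 24.5% of drought tags, 24.9% of salt tags and 23.1% of cold tags were also found in control, and these shared tags held 60.7%, 63.4% and 62.3% of the reads. Over all libraries 82.0% of the 16201527 distinct tags occurred in 1 library. For tags with at least 5 reads, 96.8% of drought, 97.1% of salt and 91.2% of cold tags were found in control. Adaptor sequence was at or below 0.900 RPM in each library.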

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

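The tests of 5.8S rRNA, of the leading 19-nt tags, of the excess of short reads, of tags found almost solely in cold and of the median ratio of other families were chosen after the results they bear on, or closely related values, had been seen. Those of GC content were set before their values were computed. Ranges printed with medians reflect the spread between families or tags, not counting error.

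miR528 was lower than control in drought (ratio 0.348) and higher in cold (ratio 3.25). miR166 was lower than control in cold (ratio 0.394) and higher in salt (ratio 2.02). With 1 library per stress, neither difference was tested. The cold call of miR166 ended with TMM factors (ratio 0.502) and relative to the median family (0.549). Its salt call ended under both of these scalings and on reads of 20 to 24 nt or of 21 nt. Reads of 31 nt, outside the gel range and the comparisons, were 0.409% of drought reads against 0.101% in control, and 17-nt reads were 0.557% of cold reads against 0.0565% in control.

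miR528 and miR408 were both higher in cold than in drought. Other 21-nt tags with the same number of G and C (51 tags) had a median cold/drought ratio of 1.37 (0.785 to 1.89), which argues against GC content as the cause. The other 23 families had a median cold/drought ratio of 0.711 (0.613 to 1.24), which argues against scaling. Variation between libraries unrelated to the stresses stays open because there is 1 library per condition, and so does a response to cold or drought, which was not tested. Such a response could not be told apart from the length of exposure, about 10 days in drought and 24 hours in cold.

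miR159 and the miR396-type tag were higher in salt, by ratios of 4.76 and 2.37. The other 23 families had a median salt/control ratio of 1.20 (1.11 to 1.48), which argues against scaling to a smaller pool of other reads for miR159. For the miR396-type tag, with its smaller ratio, scaling as a part of the cause stays open. Every salt log2 ratio moved by -0.28 relative to the median family and by -0.95 per 21-nt read. For 412 other tags of 20 to 22 nt with the same number of G and C the median was 1.28 (1.21 to 1.35), which argues against GC content for miR159. The ratio of the miR396-type tag lay below the mark set for GC content as a cause. For that tag, GC content as a part of the cause stays open as well. Variation between libraries unrelated to salt, with 1 library per condition, and a response to salt both remain open.

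Short reads and most short 5' tRNA fragments were higher in cold, though those of tRNA-Gly(GCC) of 18 to 20 nt had a ratio of 0.807. The 10 leading 19-nt tags differed 196-fold in their cold/control ratio (175 to 220) and 27.5-fold without the highest tag. That spread argues against gel size selection as the whole cause. The highest tag leads mainly through its 60221 cold reads (325 in control). Without the 2 highest the spread was 6.32-fold, between the marks set, 2-fold for gel selection and 10-fold against. Of the excess of 18 to 20 nt reads, 77.0% lay in tags with at least 10 reads in each other library. Whether reads from another organism that entered cold alone were the main source cannot be decided from this. The cut-off also admits tags far higher in cold, such as an unnamed 20-nt tag at 1009 RPM in cold, 2.02 in control, 6.93 in drought and 16.9 in salt. Gel selection as a part and more general RNA breakdown cannot be told apart from a response to cold: 5.8S rRNA fragments of 18 to 20 nt had 2.54 times the ratio of those of 24 to 27 nt (1.61 with the first search sequence), and those of 18 to 30 nt had a ratio of 0.891 (1.27 with the first). Most of these fragments reach the added 5' end (6327 RPM in control against 308 with the first). They therefore follow mainly that end and are a poor gauge of general breakdown. Another organism, as the main source or as a smaller part, stays open without a genome. Of 57 tags with at least 100 cold reads that lay at least 50-fold above every other library, 56 (0.714% of cold reads) matched no named sequence. The remaining 1 was a chloroplast tRNA-Arg(UCU) fragment. Variation between libraries unrelated to cold stays open too, with 1 library per condition.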

How the results depend on the processing

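Calls rest on 1 library per condition, so no library could be left out, and scaling is the choice that moves most results. No paired analysis was possible because each group has 1 library and the labels give no replicate numbers. Scaling to genome-matched reads and the genomic origin of reads were not run, since no genome was used. Of 454 alternative values for the 38 named family ratios, 149 could not differ, because the setting touched only the calls or another family. Of the other 305, 120 stayed within the counting interval, 185 moved beyond it and 0 called ratios changed direction. Named ratios that were not called did cross 1. With TMM factors the drought ratio went from 1.39 to 0.989 for miR159, from 1.32 to 0.937 for miR164 and from 1.04 to 0.739 for miR166. On reads of 20 to 24 nt the cold ratio of miR159 went from 0.989 to 1.12. Per 21-nt read the salt shift of -0.95 exceeded in size the log2 ratios of miR156 (0.89), miR396, miR171, miR167, miR390 and miR164 (0.15). Each of these salt ratios thus fell below 1. For these changes the cause was not tested. Scalings that moved every log2 ratio by over 0.1 were TMM (-0.49 drought, 0.35 cold, -0.24 salt), the median family (0.32, 0.48, -0.28), reads of 20 to 24 nt (0.18 cold), of 21 nt (0.14 cold, -0.95 salt) and reads without the 2 most abundant tags (0.12 salt). In drought, TMM factors gave 12 lower families, the median-family scaling 3 higher, and a 1.5-fold rule 4 higher and 9 lower (main: 0 and 4). In cold, reads of 20 to 24 nt and of 21 nt each gave 4 lower, TMM 3 lower, the median-family scaling 5 higher and 0 lower, and allowing 2 substitutions 5 higher (main: 3 and 7). In salt, 21-nt reads gave 1 higher and 3 lower, TMM 1 higher, the median-family scaling 1 higher, 2 substitutions 5 higher and a 1.5-fold rule 8 higher (main: 3 and 0). The 2 alternatives chosen after seeing the data, counting the miR396-type tag in its family and leaving the 2 most abundant tags out of the total, each gave 4 higher families in salt (miR396 joined with the first, miR156 with the second) and left the drought and cold counts at 0 and 4 and at 3 and 7. The first took the miR396 ratio from 0.574 to 0.552 in drought, from 0.391 to 0.205 in cold and from 1.56 to 2.30 in salt. miR1432 had 0 reads with exact mature sequences or up to 2 substitutions, so it has no value there, and each left 3 lower families in drought. Scalings of the ratios between stresses were chosen after seeing the data. Drought against cold (main: 5 and 6) had 0 higher and 10 lower with TMM factors. Drought against salt (main: 0 and 9) had 3 higher and 0 lower per 21-nt read and 2 and 0 relative to the median family. Cold against salt (main: 2 and 9) had 7 and 2 per 21-nt read, 4 and 5 relative to the median family, 3 and 6 with TMM factors, and 1 and 9 on reads outside the families. Other definitions of a family were not run for these ratios. The 24-nt share in control, drought, cold and salt was 67.5%, 64.1%, 60.9% and 64.7% of distinct tags, 58.4%, 51.8%, 51.5% and 46.5% of reads of 20 to 24 nt, and 44.0%, 36.8%, 30.7% and 30.6% without tags read a single time. The 24-nt to 21-nt ratio, in the same order, was 14.3, 11.7, 9.84 and 10.2 for distinct tags, 6.42, 5.93, 5.13 and 3.25 without the families, and 11.3, 8.43, 6.79 and 7.04 without the 100 most abundant tags of each length, so that cold, not salt, was then lowest by 2 of these 3 counts. Fixed 5' tRNA fragments stood at 2840, 4605, 6109 and 2115 RPM of reads outside the families (main: 2752, 4406, 5967 and 1933). Tags with at least 5 reads were found in control in 96.8% (drought), 91.2% (cold) and 97.1% (salt). The development and hormone list holds 15 of the 25 families that set the median family, so its values under that scaling are partly built in. For the development and hormone list the median log2 ratio was 0.32 (drought, which TMM factors moved the other way, by -0.49), -0.033 (cold) and 0.043 (salt) relative to the median family, -0.37 (cold) and -0.63 (salt, where the sign turned) per 21-nt read, and 0.56 (salt) with exact mature sequences. For the copper list in cold it was 1.88, 1.54 and 1.71 under the same 3 alternatives, and in salt -0.96 per 21-nt read. For the nutrient list it was -0.32 (drought) and -0.26 (salt) relative to the median family and -0.94 (salt) per 21-nt read. Depth limits miR398 and miR399, whose intervals are the widest of the named families, and families under 100 reads cannot be called.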

Other observations

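The items in this part were chosen after their values were seen, and no explanation is offered for them. The 5' fragments of 3 chloroplast tRNA sequences, recognised by sequences known from land plants and picked for their values, were more abundant in cold. The fixed tRNA-His sequence without the extra G had 54 reads in cold and 52 in control (ratio 1.11, interval 0.748 to 1.66). Its search sequence is too long to count reads of 18 to 20 nt, so that ratio does not cover the short fragments. Fragments of tRNA-Arg(ACG) stood at 26368 RPM in cold against 1253 in control (ratio 21.05), 601 in drought and 2100 in salt. Those of tRNA-Arg(UCU) stood at 5034 against 58.4 RPM (ratio 86.3, interval 80.3 to 92.8), and those of tRNA-His carrying its extra 5' G at 2713 against 246 RPM (ratio 11.05). In drought the same 3 had ratios of 0.480, 0.592 and 0.523. A 19-nt tag with a tRNA-like 5' end, GACCGCATAGCGCAGTGGA, followed by its longer forms, had ratios of 2.87 in cold, 2.31 in salt and 0.414 in drought.

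The star strand of miR156 stood at 564 RPM in cold against 4830 in control (ratio 0.117), while mature miR156 stood at 659 against 344 RPM. In drought and salt the star strand had ratios of 1.23 and 1.21. The 22-nt forms of miR167 differed: TGAAGCTGCCAGCATGATCTGA had a cold ratio of 0.224 and TGAAGCTGCCAGCATGATCTGG of 2.49. In drought these ratios were 2.34 and 1.11.

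Forms lacking the last 3' base were relatively more frequent in cold for some families. Their reads came to 6.61% of those of the full miR159 tag in cold against 1.65% in control, 2.96% against 0.777% for miR168 and 11.8% against 4.49% for miR164. Among the 10 most abundant families the share was above control beyond the counting interval for 6 in cold (miR156, miR159, miR164, miR167, miR168 and miR390), 1 in drought and 0 in salt, and below it for 0, 5 and 3. For miR167 the shortened sequence is shared by both 22-nt forms and is itself a listed mature sequence, so its share there does not measure shortening. Without that family the cold count was 5 of 9. The shortened forms of the other 9 families are 20-nt reads, which made up 6.33% of all reads in cold against 2.21% in control. The median cold ratio of 90 tags of 20 nt outside the families was 4.01, and the shares above were not corrected for this.

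A nested series of tags that starts with TAATTCATGATCTGGCATG, of unassigned origin, stood at 6069 RPM in control and 4853 in cold, but at 1232 in drought and 745 in salt. Abundant tags of 22 and 21 nt that start further 5' and overlap the start of this series differed less. The 22-nt tag stood at 3417 RPM in control, 2819 in drought, 4046 in cold and 2018 in salt. The 21-nt tag stood at 2149, 1519, 2949 and 1448 RPM in the same order. The size of the drop in drought and salt thus holds for the 5' end of the series, not for all tags overlapping it. Single-base variants of the main miR159 tag summed to 4.87% of its reads in control, 5.53% in drought, 5.44% in cold and 4.22% in salt. The variant A11C alone made up 0.424%, 0.348%, 1.16% and 0.799%. For miR168, variant A12C made up 0.478%, 0.406%, 1.06% and 1.84% in the same order.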
